A study of Mus musculus with 8 samples.

How the data were processed

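The series measured gene expression in the thoracic annulus fibrosus of WT and ENT1-null mice at 2 and 6 months, with 2 arrays per group. Per the labels' protocols, each array held a pool of annulus tissues, and biotin-labelled cRNA was made from 200 ng of total RNA extracted with Trizol. Per the submitters' processing notes the values were made by RMA, which corrects background, normalizes the quantiles between arrays and sums the probes of a probe set. The deposited values are on the log2 scale, 1 per probe set and array, and the authors' RMA version and the array's design version and genome build are not given in the sources used here. The values ran from 2.48 to 13.8 and array medians from 6.77 to 6.82. Genotype and age were taken from the labels, and no array was left out. Replicate numbers were not used to pair arrays, since no label ties them to a shared animal, batch or day.

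Of 41345 probe sets 23521 had 1 gene symbol, 1814 had several and 16010 had none. Each gene was read from its probe set with the highest mean, which gave 22180 genes, 1082 of them with more than 1 probe set. Genes with a mean below the 30th percentile (6.21, log2) were left out, and 15526 were tested. Gene order on the chromosomes was taken from a RefSeq gene table.

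Linear models were fitted with limma 3.58.1 in R 4.3.3. A fit with 4 group means (4 residual degrees of freedom) gave the effect of genotype at each age, their difference, and the effect of age in each genotype. A fit with genotype and age as terms (5 residual degrees of freedom) gave the effects across ages and across genotypes. Moderated statistics came from eBayes, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and adjusted p below 0.05 was called. The 35 lists, 22 of genes of a process or tissue and 13 of markers of a cell type, the comparisons and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested genes (34) were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which tests whether the genes of a list move on balance one way. List p-values were adjusted over the lists of a comparison. The sex-linked list had 3 genes and was not tested.

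The genes named were Slc29a1, and for each comparison the 12 largest rises and 12 largest falls (5 and 5 for the interaction) among genes that passed and whose arrays did not overlap between the groups. With fewer than 10 such calls, the 10 highest and 10 lowest moderated statistics were taken, as values. To these were added the 4 members of each called list with the largest statistic in its direction, and the 2 with the largest statistic in 5 lists chosen for the study's question. Predicted genes, olfactory and vomeronasal receptors, microRNAs and small nucleolar RNAs were passed over for the places of the largest changes. This left out 8 called genes at 2 months, 427 at 6 months, 30 in the interaction, 244 across ages, 165 by age in ENT1-null and 3 by age across genotypes. Other genes named were chosen after their values were seen, and the text says so.

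The alternatives were no filter, a filter at the 50th percentile, quantile normalization applied again, arrays centred on their medians, all probe sets, the replicate number as a block, eBayes with trend and robust, only the arrays of the groups compared, leaving out each array, adjusted p below 0.1, and unadjusted p below 0.05 with at least a 1.5-fold difference. A covariate for marrow cells, the mean level of the neutrophil and erythroid lists (27 genes), was chosen after seeing the data. The 4 groups explained 0.888 of its variance, and genotype with age 0.859. Fits with it therefore have little power, and a lost call does not show that marrow cells made the change. The 27 genes are themselves adjusted for a level they helped to make. The fits were tested on simulated data made from the 15526 gene means and residual spreads, with 200 genes changed. Noise was drawn for each gene on its own, so that variation shared by genes, as on the real arrays, was not simulated. The figures that follow check the fits and do not give the recovery or false calls on the real arrays. At 2 months 85% of genes changed by 1 (log2) and 98% of those changed by 2 were recovered with 14 false calls, and in the interaction 65% and 96% with 11 false calls. No value was imputed.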

Results

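RNA from the thoracic annulus fibrosus, the fibrocartilage ring around the core of the intervertebral disc, was measured on 8 Affymetrix arrays in Black 6 mice. ENT1-null mice carried a deletion within Slc29a1, the gene for equilibrative nucleoside transporter 1 (ENT1), a membrane carrier of adenosine and other nucleosides. WT and ENT1-null mice were studied at 2 and 6 months of age, which gave 4 groups of 2 arrays. Each array held a pool of annulus tissues. The median of the 41345 deposited log2 values lay between 6.77 and 6.82 on every array. Across the genes, Pearson r between the 2 arrays of a group was 0.983 to 0.984, and the lowest r between any 2 arrays was 0.835 (genes are not independent replicates). Principal component 1 held 74.7% of the variance, with the 6 month ENT1-null arrays at 47.7 and 51.1, the 2 month ENT1-null arrays at 0.117 and 5.39, and the WT arrays between −35.5 and −16.0. The p-values measure the spread between pools, and it is unclear whether the pools of a group came from separate mice. With 2 arrays per group, the number of arrays limits the precision. Log2 differences are given with the SE of the limma fit, and p-values adjusted by the Benjamini-Hochberg method.

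Slc29a1, on chromosome 17, carries the deletion of the ENT1-null mice, and its level checks the genotype of each array. Its level was 10.71 and 10.69 (log2) in the 2 month WT arrays and 9.21 and 9.36 in the 2 month ENT1-null arrays, a fall of −1.41 ± 0.09 (n = 2 and 2, limma adjusted p = 0.00724). This call ended without 2 month WT replicate 1 (−1.40), without 2 month ENT1-null replicate 1 (−1.34) or 2 (−1.48), and, at −1.41, with all probe sets or only the groups compared. At 6 months it was 10.34 and 10.43 in WT and 8.90 and 8.80 in ENT1-null, a fall of −1.53 ± 0.09 (limma adjusted p = 0.000354). The fall differed between the ages by −0.12 ± 0.13 (limma adjusted p = 0.599), a value that lay between −0.05 without 2 month ENT1-null replicate 2 and −0.19 without 2 month ENT1-null replicate 1. Without 6 month WT replicate 2 that difference was −0.07, as it was without 6 month ENT1-null replicate 2. Across both ages Slc29a1 fell by 1.47 ± 0.07 (4 against 4 arrays, limma adjusted p = 0.000304). Its other probe set, with a mean of 4.77 and so under the filter level, gave −0.11 at 2 and −0.16 at 6 months. The level left in ENT1-null lay above the array medians. The deletion lies within the gene, and which part each probe set reads was not examined. Among the other members of the family at 6 months, Slc29a3 rose by 0.35 ± 0.09 (adjusted p = 0.015), Slc29a2 gave −0.20 (adjusted p = 0.2) and Slc29a4 gave 0.12 (adjusted p = 0.407). These 3 genes were chosen after their values were seen. With a covariate for marrow cell markers, also chosen after seeing the data, Slc29a1 gave −1.33 at 2 and −1.40 at 6 months and did not pass.

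**Figure D1:**
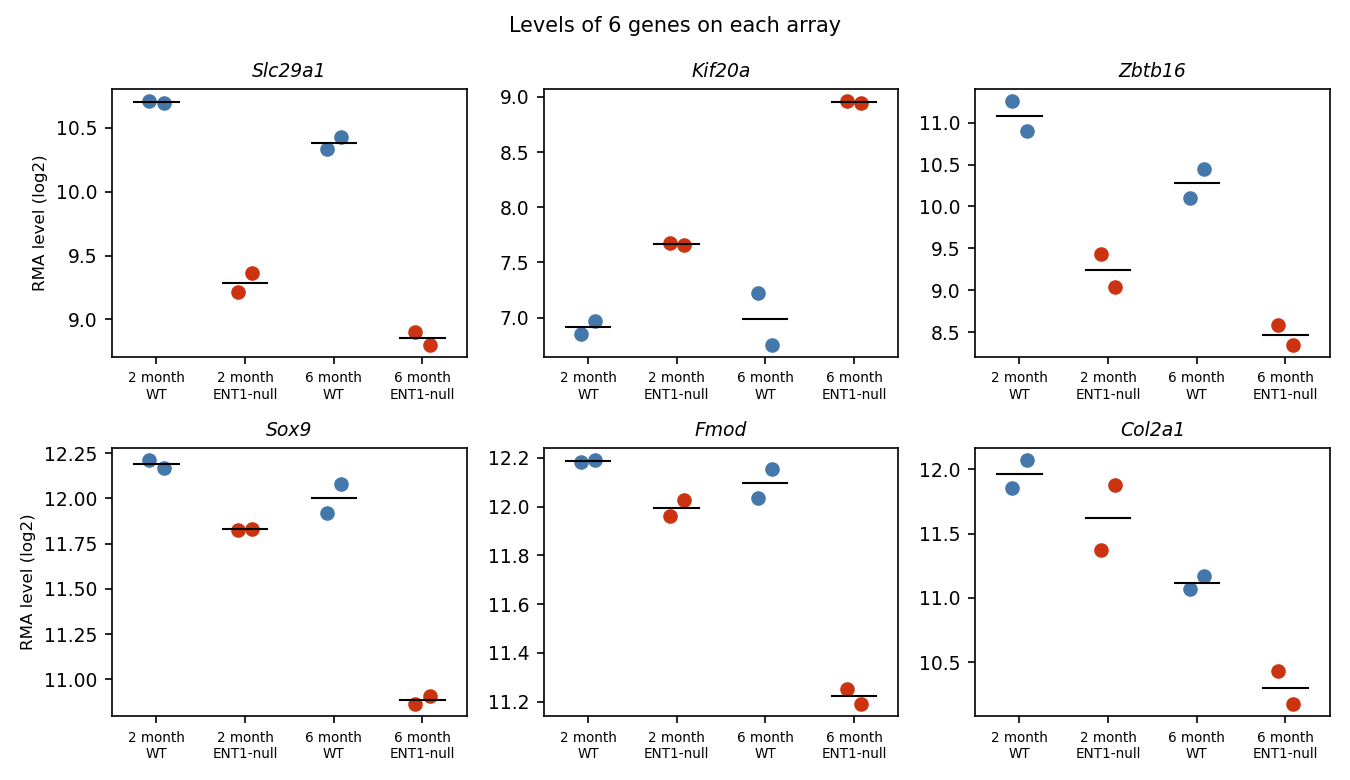
RMA level (log2) on the y axis of Slc29a1, Kif20a, Zbtb16, Sox9, Fmod and Col2a1 in the 4 groups on the x axis, with each point 1 array (blue WT, red ENT1-null) and black lines the group means. Slc29a1 was 10.34 or more in every WT array and 9.36 or less in every ENT1-null array.

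The comparison of ENT1-null with WT at 2 months (2 against 2 arrays) asks which annulus genes change with ENT1 loss in young mice, genes of cell proliferation among them, which the series title names. Among the 106 genes that changed were genes of cell division: Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose by 1.57 ± 0.21, Cenpk, a kinetochore protein, by 1.42 ± 0.18 and Stil, a centriole protein, by 1.09 ± 0.17. Genes of blood cells rose beside them: Epx, the peroxidase of eosinophils, by 1.91 ± 0.28, Ccr3, the eotaxin receptor, by 1.41 ± 0.18 and Klf1, an erythroid transcription factor, by 1.32 ± 0.20. Nxpe2 had the largest rise among the genes named by rule, 1.99 ± 0.30. The largest such falls were those of Sectm1b (−2.31 ± 0.19), Serpina6, the corticosteroid-binding globulin (−2.04 ± 0.24), Zbtb16, a zinc finger transcription factor (−1.84 ± 0.19), Angptl7 (−1.71 ± 0.27) and Tprg (−1.68 ± 0.15). Stc2, a secreted stanniocalcin, fell by 1.22 ± 0.13, Glp1r, the receptor of glucagon-like peptide 1, by 1.17 ± 0.16 and Alpl, the tissue-nonspecific alkaline phosphatase of mineralizing tissue, by 0.79 ± 0.10. Each of these genes had both ENT1-null arrays beyond both WT arrays, and their adjusted p lay between 0.0224 and 0.0463 (limma).

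Of the 15526 genes tested at 2 months, 46 were higher and 60 lower (limma), and 3008 had an unadjusted p below 0.05. The arrays of the genotypes did not overlap in 8113 genes (52.3%), against 33.3% by chance. Arrays centred on their medians gave 96 higher and 65 lower genes, a share of higher genes of 59.6% against 43.4%. The count rested on single arrays: it was 0 without 2 month WT replicate 1 or 2 month ENT1-null replicate 2, so that every call named ended there. It was 1 without 2 month ENT1-null replicate 1 or either 6 month ENT1-null array, 299 (215 higher, 84 lower) without either 6 month WT array and 358 (307 higher, 51 lower) without 2 month WT replicate 2, so that the larger direction turned. The count was also 0 with all probe sets or with only the groups compared. It was 0 too with the level of marrow cell markers as a covariate, chosen after seeing the data. The groups explained 0.888 of the variance of that level, so that this 0 cannot tell marrow cells from genotype. With no filter the count was 29 (11 higher, 18 lower), where of the genes named above Cenpk, Ccr3, Sectm1b, Serpina6, Zbtb16, Tprg, Stc2 and Slc29a1 passed.

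At 2 months all 30 measured genes of mitosis and G2/M lay above 0 (median 1.24). Of these, 1 passed among all genes, 29 did not, and 30 were higher adjusted over the list alone (camera adjusted p = 7.51e-26, adjusted p = 0.391 with an estimated correlation). Ect2, a regulator of cytokinesis, gave 1.41 ± 0.24 (adjusted p = 0.054) and Aurka, a spindle kinase, 0.97 ± 0.17 (adjusted p = 0.0544). In the list of DNA replication and S phase (27 genes, median 0.64), 1 gene was higher, 26 did not pass, and 25 were higher adjusted over the list alone (camera adjusted p = 6.47e-19, adjusted p = 0.391 with an estimated correlation). Its member Mcm4, of the replicative helicase, rose by 0.74 ± 0.11, and Mcm2 gave 0.95 ± 0.16 (adjusted p = 0.054). Markers of marrow cells had high values in the same arrays. The erythroid list (9 genes) had a median of 1.73 with 1 gene higher, 8 not passing and 9 higher adjusted over the list alone (camera adjusted p = 4.09e-11, adjusted p = 0.391 with an estimated correlation). The neutrophil list (18 genes) had a median of 1.5, or 0.92 without 2 month WT replicate 1, with 0 genes past the test and 17 higher adjusted over the list alone (camera adjusted p = 3.23e-11, adjusted p = 0.57 with an estimated correlation). Of 16 macrophage genes (median 0.76, or 0.44 without 2 month WT replicate 1) none passed among all genes and 11 were higher adjusted over the list alone (camera adjusted p = 4.19e-10, adjusted p = 0.391 with an estimated correlation). With the marrow covariate the medians were 0.23 for mitosis, 0.15 for S phase and 0.14 for macrophages.

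Of 24 cartilage matrix genes at 2 months (median −0.14) none passed among all genes and 2 were lower adjusted over the list alone (camera adjusted p = 0.00754, adjusted p = 0.391 with an estimated correlation). Matn1, a cartilage matrilin, gave −0.55 ± 0.11 (adjusted p = 0.0664) and Sox9, the chondrocyte transcription factor, −0.36 ± 0.09 (adjusted p = 0.0859). The list's call ended without 2 month ENT1-null replicate 1 (−0.13) and with the marrow covariate (−0.15), and its median was −0.22 without 2 month ENT1-null replicate 2. The circadian clock list (17 genes, median −0.39) had 1 gene lower, Cry2, a repressor of the clock, which fell by 0.74 ± 0.11, 16 not passing and 3 lower adjusted over the list alone (camera adjusted p = 0.0044, adjusted p = 0.391 with an estimated correlation). Its call ended without 2 month ENT1-null replicate 2 (−0.29). The interferon response list (18 genes, median 0.39) had 1 gene higher, the RNA sensor Ifih1 (0.54 ± 0.09), 17 not passing and 7 higher adjusted over the list alone (camera adjusted p = 1.82e-06, adjusted p = 0.57 with an estimated correlation). None of 24 skeletal muscle genes passed (median 0.96, none adjusted over the list alone, camera adjusted p = 4.17e-05, adjusted p = 0.57 with an estimated correlation). That median was 0.22 without 2 month WT replicate 1, 1.61 without 2 month WT replicate 2, 1.67 without 2 month ENT1-null replicate 1 and 0.15 without 2 month ENT1-null replicate 2, where the call ended. None of the 25 genes of nucleoside transport, adenosine receptors and purine metabolism passed (median 0.04), and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0405, adjusted p = 0.57 with an estimated correlation). In that list Dck, deoxycytidine kinase, gave 1.07 ± 0.19 (adjusted p = 0.0545). Its call ended without 2 month WT replicate 1 (0.03) or 2 month ENT1-null replicate 2 (−0.02), and its median was 0.13 without 2 month WT replicate 2 or 2 month ENT1-null replicate 1. The mineralization regulators (21 genes, median −0.07, 1 lower, 20 not passing, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.417) were not called. Nor was the fibrous annulus and tendon matrix list (31 genes, median −0.08, mean 0.06, camera direction down with adjusted p = 0.729). In the fibrous list Cilp2, a cartilage intermediate layer protein, fell by 0.80 ± 0.11, 30 genes did not pass, and 1 was higher and 3 lower adjusted over the list alone. The marrow covariate also ended the calls of the circadian clock (−0.10), interferon (0.12), skeletal muscle (−0.10, camera direction up) and nucleoside lists (−0.06, camera direction up). Camera called 21 of 34 lists in all, 0 with an estimated correlation, and 11 without 2 month ENT1-null replicate 2.

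The same comparison at 6 months (2 against 2 arrays) asks which genes depend on ENT1 in older mice. The largest rises among the genes named by rule were those of immune cells: a variable segment of the immunoglobulin kappa chain (4.77 ± 1.34), Prg2, the major basic protein of eosinophils (4.28 ± 0.52), and Epx (3.94 ± 0.28). Jchain, the joining chain of secreted antibodies (3.69 ± 0.57), and Ifitm6 (3.33 ± 0.62) rose as well. Genes of skeletal muscle fell, among them Myot, myotilin of the Z disc (−3.15 ± 0.60), Myh4, a fast myosin (−3.12 ± 0.75), and Ttn, titin (−2.58 ± 0.61). Sectm1b (−3.07 ± 0.19), Serpina6 (−3.01 ± 0.24) and Tprg (−2.61 ± 0.15) fell as they had at 2 months. Every gene of mitosis in the list rose, and cartilage genes such as Sox9 (−1.11 ± 0.09) fell. Adjusted p of the genes in this paragraph lay between 0.000354 and 0.0264 (limma), and in each both ENT1-null arrays lay beyond both WT arrays. The kappa segment did not pass without 6 month WT replicate 2 (2.81) or without 6 month ENT1-null replicates 1 (4.74) or 2 (4.80). Myh4 did not pass without 6 month WT replicate 1 (−2.78) or 6 month ENT1-null replicate 1 (−2.56), nor did Ttn without either 6 month WT array (−2.61 and −2.55) or 6 month ENT1-null replicate 1 (−1.92).

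At 6 months 6022 genes changed (limma), 3295 higher and 2727 lower, of which 1352 differed at least 2-fold, and 7507 had an unadjusted p below 0.05. Quantile normalization applied again turned the larger direction (2923 higher, 3059 lower), and centred arrays gave 3606 higher and 2293 lower. The arrays of the genotypes did not overlap in 11231 genes (72.3%), against 33.3% by chance. The count was 3670 without 6 month WT replicate 2 and 0 with the marrow covariate. The groups explained 0.888 of the variance of the marrow marker level, which leaves little of it to tell marker level from group.

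All 30 mitosis and G2/M genes rose at 6 months (median 2.22), also adjusted over the list alone (camera adjusted p = 5.22e-16, adjusted p = 0.496 with an estimated correlation). Kif20a, a kinesin of cytokinesis, rose by 1.96 ± 0.14 and Cenpf, a kinetochore protein, by 1.68 ± 0.13 (adjusted p = 0.000383 for both). Of 27 genes of DNA replication and S phase (median 1.47), 26 rose and 1 did not pass, with 26 higher adjusted over the list alone (camera adjusted p = 9.93e-14, adjusted p = 0.496 with an estimated correlation). Rrm1, a ribonucleotide reductase subunit, rose by 1.87 ± 0.15 and Mcm4 by 1.58 ± 0.11 (adjusted p = 0.000383 for both). Marrow and immune cell markers rose in the same arrays. All 18 neutrophil genes were higher (median 2.60, 18 adjusted over the list alone, camera adjusted p = 8.83e-07, adjusted p = 0.525 with an estimated correlation), among them Cd177 (2.68 ± 0.35). All 9 erythroid genes were higher (median 2.20, 9 adjusted over the list alone, camera adjusted p = 1.61e-05, adjusted p = 0.496 with an estimated correlation), among them Klf1 (1.92 ± 0.20). Of 16 macrophage genes (median 1.47) 15 were higher and 1 did not pass, with 15 higher adjusted over the list alone (camera adjusted p = 8.22e-07, adjusted p = 0.496 with an estimated correlation). B cell genes (12, median 0.97) were higher in 9 cases and did not pass in 3, with 9 higher adjusted over the list alone (camera adjusted p = 0.00128, adjusted p = 0.496 with an estimated correlation). Of 7 T and NK cell genes (median 1.16) 5 were higher and 2 did not pass, with 6 higher adjusted over the list alone (camera adjusted p = 0.00349, adjusted p = 0.496 with an estimated correlation). Interferon response genes (18, median 0.85) were higher in 15 cases and lower in 1, 2 did not pass, and 16 were higher and 1 lower adjusted over the list alone (camera adjusted p = 1.07e-05, adjusted p = 0.496 with an estimated correlation). Ifih1 rose by 1.22 ± 0.09. Among 11 osteoclast genes (median 1.26) 10 were higher and 1 lower, the same counts adjusted over the list alone (camera adjusted p = 0.00359, adjusted p = 0.525 with an estimated correlation). With the marrow covariate, where the group and the marker level overlap, the medians were 0.97 for mitosis, 0.70 for S phase, 0.58 for macrophages and 0.45 for interferon. The calls of B cells (0.19), T and NK cells (0.34) and osteoclasts (0.41) ended with it.

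**Figure D2:**
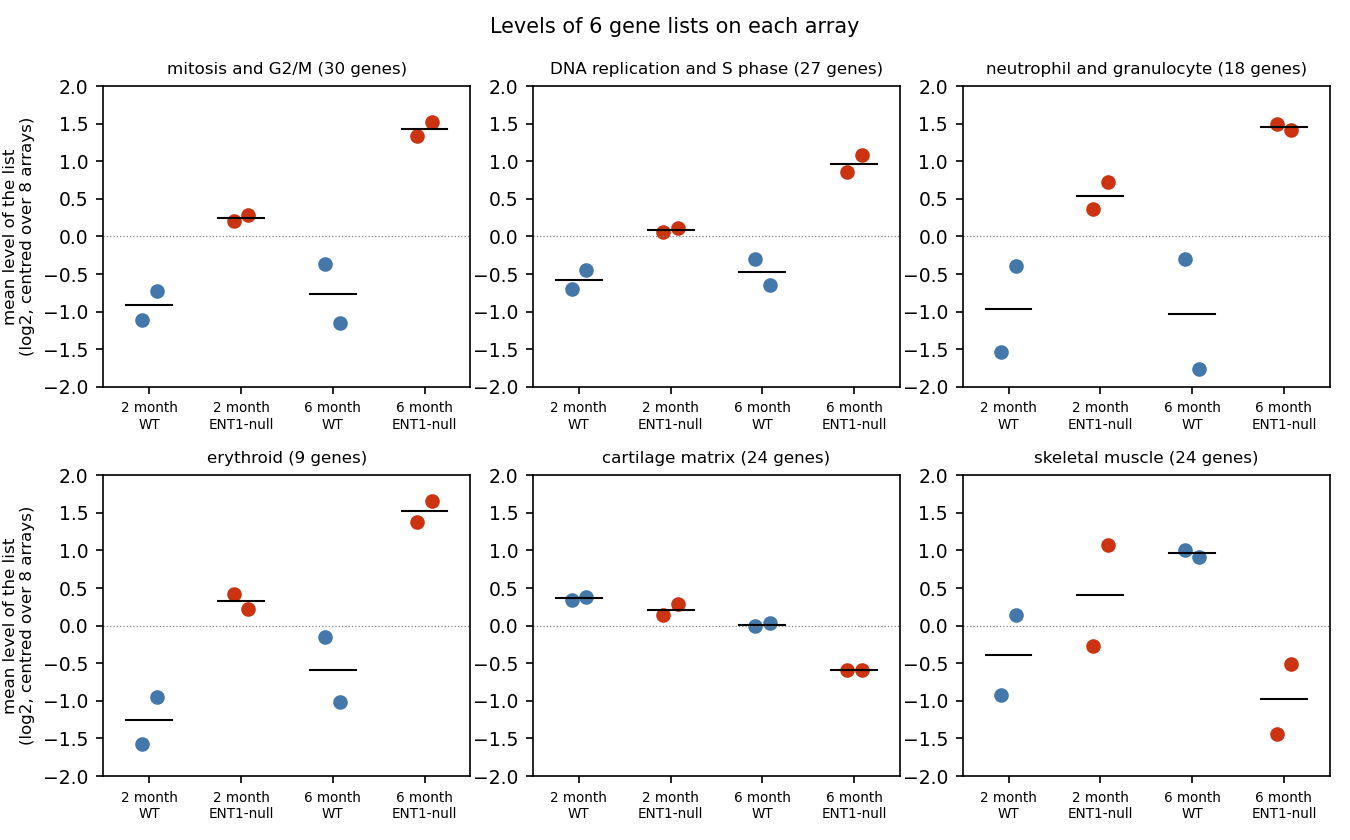
Mean level of the genes of a list (log2, centred over the 8 arrays) on the y axis for mitosis and G2/M, DNA replication and S phase, neutrophil, erythroid, cartilage matrix and skeletal muscle genes in the 4 groups on the x axis, with each point 1 array and black lines the group means. The 6 month ENT1-null arrays were highest for mitosis (1.34 and 1.53) and neutrophil genes (1.5 and 1.41) and lowest for cartilage genes (−0.60 and −0.59).

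Matrix genes fell in the ENT1-null annulus at 6 months, while the marrow markers rose as given above. Of 24 cartilage matrix genes (median −0.67) 17 were lower and 7 did not pass, with 20 lower adjusted over the list alone (camera adjusted p = 1.19e-07, adjusted p = 0.194 with an estimated correlation). Sox9 fell by 1.11 ± 0.09, Ucma by 0.92 ± 0.09, Sox5, its partner in the chondrocyte programme, by 0.87 ± 0.08, and Cnmd, chondromodulin, by 0.84 ± 0.07 (adjusted p between 0.000383 and 0.000453). In the fibrous annulus and tendon matrix list (31 genes, median −0.36) 3 genes were higher, 16 lower and 12 did not pass, with 3 higher and 18 lower adjusted over the list alone (camera adjusted p = 0.000894, adjusted p = 0.496 with an estimated correlation). Fmod, fibromodulin, fell by 0.87 ± 0.08 and Mkx, the tendon transcription factor Mohawk, by 1.40 ± 0.15 (adjusted p = 0.00045 and 0.000583). The 3 higher genes were Col1a1 (1.35 ± 0.33) and Col1a2 (1.19 ± 0.25), the chains of type I collagen, and Lum, lumican (0.59 ± 0.16, adjusted p = 0.0226), chosen after their values were seen. The collagen and matrix biosynthesis list (26 genes, median −0.43) had 13 lower, 13 not passing, and 13 lower adjusted over the list alone (camera adjusted p = 5.99e-05, adjusted p = 0.496 with an estimated correlation). Its falls included Has2, a hyaluronan synthase (−1.42 ± 0.14), and Plod2, a lysyl hydroxylase (−1.27 ± 0.12), with adjusted p = 0.000503 and 0.000439. The skeletal muscle list (24 genes, median −2.08) had 20 lower, 4 not passing and 22 lower adjusted over the list alone (camera adjusted p = 3.6e-06, adjusted p = 0.525 with an estimated correlation). The marrow covariate gave medians of −0.65 for cartilage, −0.59 for the fibrous list and −3.67 for muscle.

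Of 33 genes of TGF-beta and BMP signalling at 6 months (median −0.49) 2 were higher, 18 lower and 13 did not pass, with 3 higher and 20 lower adjusted over the list alone (camera adjusted p = 9.11e-05, adjusted p = 0.194 with an estimated correlation). Bmp6, a bone morphogenetic protein, fell by 1.49 ± 0.11 and Bmpr1b, a BMP receptor, by 1.13 ± 0.12 (adjusted p = 0.000383 and 0.000511). Of 29 Wnt genes (median −0.25) 2 were higher, 11 lower and 16 did not pass, with the same 2 and 11 as counts adjusted over the list alone (camera adjusted p = 0.00282, adjusted p = 0.434 with an estimated correlation). Sfrp5 (−1.51 ± 0.11) and Wif1 (−1.03 ± 0.12), both secreted inhibitors of Wnt, were among the falls (adjusted p = 0.000383 and 0.00066). Immediate early genes (20, median −0.55) were lower in 8 cases and did not pass in 12, with 10 lower adjusted over the list alone (camera adjusted p = 0.000727, adjusted p = 0.523 with an estimated correlation). Klf4 fell by 1.35 ± 0.10. The circadian clock list (17 genes, median −0.71) had 5 lower and 12 not passing, with 5 lower adjusted over the list alone (camera adjusted p = 0.00299, adjusted p = 0.434 with an estimated correlation). Its median was −0.44 without 6 month WT replicate 2 and −0.35 without 6 month ENT1-null replicate 1. Hypoxia and glycolysis genes (24, median −0.31, or −0.20 without 6 month WT replicate 2) had 2 higher, 10 lower and 12 not passing, with 2 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.00211, adjusted p = 0.525 with an estimated correlation). Among 10 hypertrophic cartilage genes (median −0.39) 1 was higher, 4 were lower and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0294, adjusted p = 0.565 with an estimated correlation). This call ended without 6 month WT replicate 2 (−0.32) or 6 month ENT1-null replicate 1 (−0.36). The calls of the clock (−0.38), hypoxia (−0.16) and hypertrophic cartilage lists (−0.27) ended with the marrow covariate. Not called were ERK pathway targets (27 genes, median −0.05, 5 higher, 6 lower, 16 not passing, 8 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.563). Nor were inflammatory cytokines and NF-kappaB targets (20 genes, median 0.10, 6 higher, 2 lower, 12 not passing, the same 6 and 2 as counts adjusted over the list alone, camera adjusted p = 0.276).

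Genes of nucleoside and adenosine metabolism moved both ways at 6 months. Of 25 (median 0.21) 12 were higher, 5 lower and 8 did not pass, with the same 12 and 5 as counts adjusted over the list alone (camera adjusted p = 0.0294, adjusted p = 0.525 with an estimated correlation). The rises included Dck (2.15 ± 0.19), Ampd3, an AMP deaminase (1.76 ± 0.15), Dpp4 (1.38 ± 0.12), and Slc28a2, a concentrative nucleoside transporter (1.14 ± 0.13), with adjusted p between 0.000426 and 0.000712. The 5 lower genes, chosen after their values were seen, were Ampd1, the AMP deaminase of muscle (−2.08 ± 0.50), Adk, adenosine kinase (−0.88 ± 0.09), Nt5e, which makes adenosine from AMP (−0.69 ± 0.09), Ak1 (−0.62) and P2rx7 (−0.37). The list's call ended without 6 month ENT1-null replicate 2, where the median was 0.27, and with the marrow covariate (0.18). Of 21 mineralization regulators (median −0.18) 3 were higher, 8 lower and 10 did not pass, with 4 higher and 9 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.115). Alpl fell by 0.79 ± 0.10 and Vkorc1, a vitamin K epoxide reductase, by 0.76 ± 0.09 (adjusted p = 0.00109 and 0.000833). Among 18 endothelial genes (median 0.39) 3 were higher and 15 did not pass, with 1 higher adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.625 with an estimated correlation), and the marrow covariate turned the median to −0.035. Camera called 21 of 34 lists and, with an estimated correlation, 0.

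Whether the effect of ENT1 loss differs between 2 and 6 months was asked by the interaction of genotype and age, the effect at 6 months minus that at 2 months. The rise of Epx was larger at 6 months by 2.02 ± 0.39 and that of Kif20a by 1.21 ± 0.20, and the effect on Cnmd was lower by 0.78 ± 0.11 and that on Has2 by 1.32 ± 0.20. The effect on Myot was lower by 4.30 ± 0.85, with 1.15 ± 0.60 at 2 months (adjusted p = 0.348) and −3.15 ± 0.60 at 6 months. The adjusted p of these 5 genes in the interaction lay between 0.0383 and 0.0429. In all 691 genes differed (limma), 398 with a higher and 293 with a lower effect at 6 months. In the interaction 4186 had an unadjusted p below 0.05. Quantile normalization applied again gave 299 higher and 407 lower, a share of higher genes of 42.4% against 57.6%. The count was 319 (242 higher, 77 lower) without 6 month WT replicate 1, 21 (4 higher, 17 lower) without 2 month ENT1-null replicate 1, and 0 without each of the other arrays, with all probe sets or with the marrow covariate, so that the calls of the genes named here ended there. With no filter it was 11 (7 higher, 4 lower), none of these 5 genes among them.

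The effect on mitosis and G2/M genes was higher at 6 months by a median of 1.13, with 6 of 30 genes higher, 24 not passing and 19 higher adjusted over the list alone (camera adjusted p = 4.94e-09, adjusted p = 0.633 with an estimated correlation). In the S phase list (median 0.85) 7 of 27 were higher and 20 did not pass, with 25 higher adjusted over the list alone (camera adjusted p = 1.4e-09, adjusted p = 0.537 with an estimated correlation). Cartilage genes had a median of −0.49, or −0.30 without 2 month ENT1-null replicate 2, with 8 of 24 lower, 16 not passing and 11 lower adjusted over the list alone (camera adjusted p = 4.06e-09, adjusted p = 0.0986 with an estimated correlation). Genes of TGF-beta and BMP signalling had a median of −0.34, with 6 of 33 lower, 27 not passing and 10 lower adjusted over the list alone (camera adjusted p = 6e-07, adjusted p = 0.0986 with an estimated correlation). The effect on Bmp2 was lower by 1.12 ± 0.15. In the same interaction the erythroid list gave 0.56 (camera adjusted p = 0.121) and the skeletal muscle list −3.09, with 1 of 24 lower, 23 not passing and 22 lower adjusted over the list alone (camera adjusted p = 2.32e-13, adjusted p = 0.489 with an estimated correlation). The mitosis median was 0.74 with the marrow covariate. Camera called 19 of 34 lists, 0 with an estimated correlation.

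The effects at the 2 ages, which share no arrays, were set side by side across the 15526 genes. Pearson r was 0.709 and Spearman rho 0.589 (across genes, which are not independent replicates), and 71.0% of genes had the same sign. Medians of the marrow marker lists lay above 0 at both ages, 1.5 and 2.60 for the neutrophil and 1.73 and 2.20 for the erythroid list. Most genes of both lists did not pass at 2 months. The difference between the 2 WT arrays of an age, the array with the higher marrow marker level minus the other, had r = 0.447 at 2 months with the genotype effect at 6 months and r = 0.533 at 6 months with the effect at 2 months (across genes). Of the 46 genes higher at 2 months 45 were also higher at 6 months, where 9.76 are given by lists that overlap at random, and of the 60 lower genes 50 were also lower, against 10.5. The calls at both ages use the same residual spread of a gene, pooled over all arrays. A gene with a small spread passes more easily at both ages, so that the random counts are not a fair baseline. Among the 106 genes 72 had the larger effect at 6 months, with a median size of 1.24 against 0.84, and 25 also passed in the interaction.

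**Figure D3:**
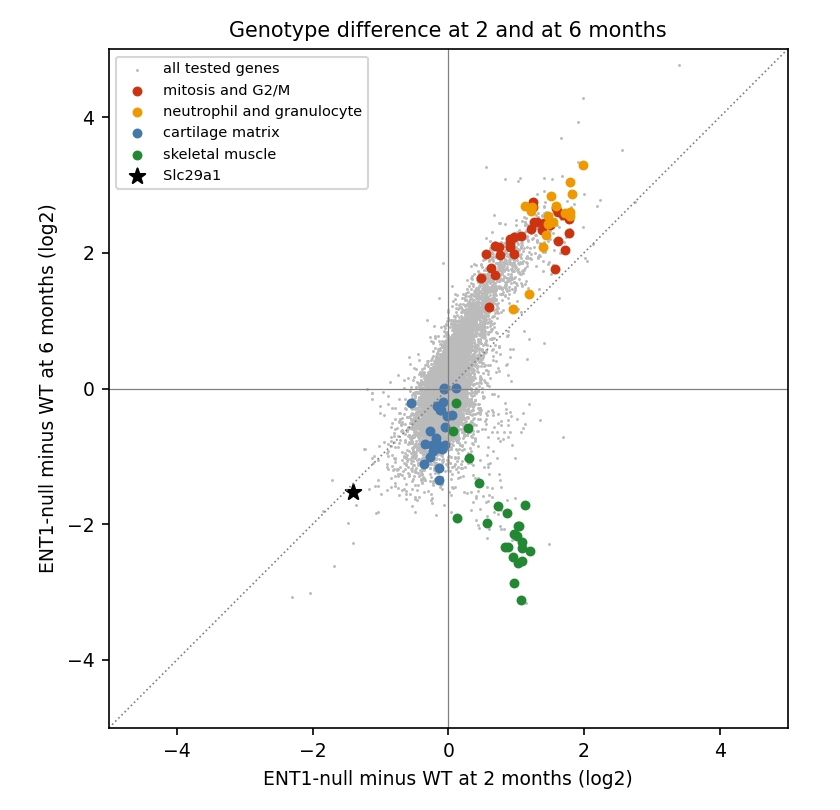
Effect of genotype (ENT1-null minus WT, log2) at 2 months on the x axis and at 6 months on the y axis, with each point 1 gene: grey all genes tested, red mitosis and G2/M, orange neutrophil, blue cartilage matrix, green skeletal muscle, a star Slc29a1, and a dotted line of equal effects. The mitosis genes had medians of 1.24 at 2 months and 2.22 at 6 months, and the skeletal muscle genes 0.96 and −2.08.

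The effect of genotype across both ages (4 against 4 arrays, with age as a term) asks which genes depend on ENT1 whatever the age. Prg2 rose by 3.13 ± 0.54, Epx by 2.92 ± 0.40 and Kel, an erythroid surface protein, by 2.44 ± 0.27. Sectm1b fell by 2.69 ± 0.19, Serpina6 by 2.53 ± 0.24, Tprg by 2.15 ± 0.19, Zbtb16 by 1.82 ± 0.13 and Glp1r by 1.32 ± 0.12, and Alpl fell by 0.79 ± 0.07 (adjusted p between 0.00296 and 0.00892). In each of these except Alpl the 4 ENT1-null arrays lay beyond the 4 WT arrays. In all 3809 genes changed (limma), 1993 higher and 1816 lower, and 6214 had an unadjusted p below 0.05. Quantile normalization applied again turned the larger direction (1868 higher, 2129 lower), and centred arrays gave 2133 higher and 1411 lower. The arrays of the genotypes did not overlap in 3570 genes (23.0%), against 2.86% by chance. The count was 2451 without 2 month WT replicate 1, 1390 without 6 month WT replicate 1, 1779 without 6 month WT replicate 2, 1664 and 1865 without 6 month ENT1-null replicates 1 and 2, and 0 with the marrow covariate.

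Across ages all 30 mitosis and G2/M genes rose (median 1.72, 30 adjusted over the list alone, camera adjusted p = 1.52e-19, adjusted p = 0.503 with an estimated correlation), with Ube2c at 1.66 ± 0.15 and Ccnb2, cyclin B2, at 2.04 ± 0.25. Of 27 S phase genes (median 1.04) 25 rose and 2 did not pass, with 25 adjusted over the list alone (camera adjusted p = 9.44e-15, adjusted p = 0.503 with an estimated correlation). The neutrophil (median 2.00) and erythroid (median 1.97) lists moved with them: all 18 and all 9 genes rose, also adjusted over the list alone (camera adjusted p = 8.03e-11 and 8.5e-09, each adjusted p = 0.503 with an estimated correlation). Cartilage genes (24, median −0.44) had 11 lower, 13 not passing and 16 lower adjusted over the list alone (camera adjusted p = 2.72e-05, adjusted p = 0.503 with an estimated correlation), a call that ended with the marrow covariate (−0.14). Of 17 circadian clock genes (median −0.37) 6 were lower and 11 did not pass, with 8 lower adjusted over the list alone (camera adjusted p = 0.00179, adjusted p = 0.503 with an estimated correlation). Cry2 fell by 1.00 ± 0.12. Interferon genes (18, median 0.51) had 13 higher, 1 lower and 4 not passing, with 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.35e-07, adjusted p = 0.503 with an estimated correlation). Rsad2, viperin, rose by 1.60 ± 0.17. Among 28 genes of heat shock and the unfolded protein response (median −0.26, or −0.20 without 6 month ENT1-null replicate 2, where the call ended) 3 were higher, 10 lower and 15 did not pass, and 3 were higher and 14 lower adjusted over the list alone (camera adjusted p = 0.0352, adjusted p = 0.542 with an estimated correlation). With the marrow covariate the medians were 0.23 for mitosis and 0.14 for S phase, and the calls of the clock (−0.09), interferon (0.11) and heat shock lists (−0.06) ended. Camera called 20 of 34 lists, 0 with an estimated correlation, and the skeletal muscle list (median −0.58) was not called (camera adjusted p = 0.146).

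What age alone does to the annulus was asked in WT mice, 6 against 2 months (2 against 2 arrays). No gene changed (limma, lowest adjusted p = 0.119), 0 with a variance trend as well, and 2067 had an unadjusted p below 0.05. The values nearest to a change were those of Slc25a33 (−0.85 ± 0.08, adjusted p = 0.119), Matn1 (−0.89 ± 0.11), Cilp2 (−0.93 ± 0.11) and Slc38a4 (−1.10 ± 0.13) on the lower side. On the higher side were Atp1b4 (1.06 ± 0.16, adjusted p = 0.162) and Nr4a3 (1.20 ± 0.22, adjusted p = 0.192). Col2a1, the chain of type II collagen, gave −0.84 ± 0.17 (adjusted p = 0.193). The arrays of the ages did not overlap in 49.4% of genes, against 33.3% by chance. Cartilage genes had a median of −0.32 with 0 of 24 past the test and 13 lower adjusted over the list alone (camera adjusted p = 4.91e-09, adjusted p = 0.194 with an estimated correlation). The skeletal muscle list had a median of 1.55, or 0.78 without 2 month WT replicate 1, with 0 of 24 past the test and none adjusted over the list alone (camera adjusted p = 5.49e-16, adjusted p = 0.723 with an estimated correlation).

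In WT the mitosis and G2/M list had a median of 0.12 with 0 of 30 past the test and none adjusted over the list alone (camera adjusted p = 0.00233, adjusted p = 0.8 with an estimated correlation). Its median turned to −0.23 without 6 month WT replicate 1, was −0.01 without 2 month WT replicate 1, where the call ended, 0.29 without 2 month WT replicate 2 and 0.48 without 6 month WT replicate 2. The S phase list (median 0.11, 0 of 27 past the test, none adjusted over the list alone, camera adjusted p = 0.00179, adjusted p = 0.763 with an estimated correlation) turned to −0.04 without 6 month WT replicate 1. It was −0.03 without 2 month WT replicate 1, where the call ended, 0.17 without 2 month WT replicate 2 and 0.23 without 6 month WT replicate 2. Of the marrow markers the erythroid list had a median of 0.63 with 0 of 9 past the test and none adjusted over the list alone (camera adjusted p = 1.82e-06, adjusted p = 0.723 with an estimated correlation). It was 0.31 and 0.20 without replicate 1 of 2 month or of 6 month WT and 0.98 and 1.16 without replicate 2 of either. The neutrophil list had a median of −0.06 and a mean of −0.07 with the camera direction up (adjusted p = 0.494). The calls of the mitosis (−0.04, camera direction up) and S phase lists (0.03) ended with the marrow covariate. Camera called 16 of 34 lists, 0 with an estimated correlation.

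What age does in mice without ENT1 was asked in the same way (6 against 2 months, 2 against 2 ENT1-null arrays). Col9a1, a chain of type IX collagen, fell by 1.76 ± 0.16, Matn3, a cartilage matrilin, by 1.59 ± 0.19, Panx3, a pannexin of cartilage and bone cells, by 1.84 ± 0.14, and Slc38a4, an amino acid transporter, by 1.87 ± 0.13. Gpnmb, a glycoprotein of macrophages and osteoclasts, rose by 1.90 ± 0.11, Apol11b by 2.62 ± 0.36 and Il1b, interleukin 1 beta, by 1.88 ± 0.21 (adjusted p of these 7 genes between 0.0013 and 0.00409). Igkv4-91 rose by 2.95 ± 0.52, a call that ended without 2 month ENT1-null replicate 1 (2.85) or 6 month ENT1-null replicate 2 (2.74). Myot fell by 2.10 ± 0.60, and did not pass without 2 month ENT1-null replicate 2 (−1.23), 6 month ENT1-null replicates 1 (−1.59) or 2 (−2.62), or either 6 month WT array (−2.10). Slc29a1 fell by 0.44 ± 0.09 (adjusted p = 0.0136), a call that ended without replicate 2 of either ENT1-null group (−0.36 and −0.39). In WT its level was also lower at 6 months (10.34 and 10.43) than at 2 months (10.71 and 10.69), though not called. The genotype effect on it was not called as differing between the ages. In all 3442 genes changed (limma), 1853 higher and 1589 lower, and 5457 had an unadjusted p below 0.05. Quantile normalization applied again turned the larger direction (1596 higher, 1772 lower). Arrays did not overlap in 59.8% of genes, against 33.3% by chance. The larger direction also turned without 2 month ENT1-null replicate 1 (1519 genes, 637 higher), 6 month ENT1-null replicate 1 (2464 genes, 1187 higher) or 6 month ENT1-null replicate 2 (1532 genes, 728 higher). The count was 301 (118 higher, 183 lower) with the marrow covariate, of which 298 were among the 3442.

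Of 24 cartilage genes in ENT1-null (median −0.89) 20 were lower and 4 did not pass, with 22 lower adjusted over the list alone (camera adjusted p = 2.26e-14, adjusted p = 0.0778 with an estimated correlation). Frzb, a secreted Wnt inhibitor of cartilage, fell by 1.18 ± 0.10. Of 31 fibrous annulus and tendon matrix genes (median −0.55) 17 were lower and 14 did not pass, with 23 lower adjusted over the list alone (camera adjusted p = 1.13e-09, adjusted p = 0.277 with an estimated correlation). Collagen and matrix biosynthesis genes (26, median −0.58) had 18 lower, 8 not passing and 20 lower adjusted over the list alone (camera adjusted p = 7.84e-10, adjusted p = 0.277 with an estimated correlation). Mitosis and G2/M genes (30, median 1.22) had 24 higher, 6 not passing and 30 higher adjusted over the list alone (camera adjusted p = 6.46e-14, adjusted p = 0.438 with an estimated correlation). Kif20a rose by 1.28 ± 0.14. S phase genes (27, median 0.89) had 25 higher, 2 not passing and 26 higher adjusted over the list alone (camera adjusted p = 8.95e-14, adjusted p = 0.438 with an estimated correlation). Beside these, 7 of 9 erythroid genes were higher and 2 did not pass (median 1.21, 9 adjusted over the list alone, camera adjusted p = 7.18e-05, adjusted p = 0.438 with an estimated correlation). Of 18 neutrophil genes (median 0.95) 2 were higher and 16 did not pass, none adjusted over the list alone (camera adjusted p = 0.00234, adjusted p = 0.652 with an estimated correlation). The skeletal muscle list (median −1.56, or −0.80 without 2 month ENT1-null replicate 2 and −0.99 without 6 month ENT1-null replicate 1) had 1 of 24 lower, 23 not passing and 1 lower adjusted over the list alone (camera adjusted p = 1.18e-05, adjusted p = 0.51 with an estimated correlation). The marrow covariate gave a mitosis median of 0.63. Camera called 23 of 34 lists, 0 with an estimated correlation.

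Age across both genotypes (4 against 4 arrays, with genotype as a term) asks what age does whatever the genotype. Genes of cartilage and mineralizing tissue were among the 77 that changed: Col10a1, the collagen of hypertrophic cartilage, fell by 1.10 ± 0.14, Col2a1 by 1.08 ± 0.15, Cilp2 by 1.03 ± 0.09, Epyc, a small proteoglycan of cartilage, by 0.76 ± 0.07 and Alpl by 0.69 ± 0.07. Ddit4, a stress-induced inhibitor of mTOR signalling, fell by 1.75 ± 0.25 and Slc38a4 by 1.48 ± 0.16. Adjusted p of these genes lay between 0.0226 and 0.042, and the arrays of the ages overlapped in Cilp2 and Alpl. Of the 77 genes (limma) 6 were higher and 71 lower, and 3418 had an unadjusted p below 0.05. The arrays of the ages did not overlap in 4.77% of genes, against 2.86% by chance. The count was 610 (273 higher, 337 lower) without 6 month WT replicate 2 and 320 (177 higher, 143 lower) without 2 month WT replicate 2, so that the share of falls was not kept. It was 0 without each of the other 6 arrays or with the marrow covariate, so that these calls ended there, 40 with no filter, 157 with the stricter filter and 9 (3 higher, 6 lower) with all probe sets.

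Across genotypes 3 of 24 cartilage genes were lower with age and 21 did not pass (median −0.58), with 21 lower adjusted over the list alone (camera adjusted p = 6.29e-14, adjusted p = 0.37 with an estimated correlation). Collagen and matrix biosynthesis genes (26, median −0.41) had 2 lower, 24 not passing and 17 lower adjusted over the list alone (camera adjusted p = 9.9e-10, adjusted p = 0.37 with an estimated correlation). None of 30 mitosis genes passed, or passed adjusted over the list alone (median 0.68, or 0.16 with the marrow covariate, camera adjusted p = 2.11e-13, adjusted p = 0.37 with an estimated correlation). Of the marrow markers, none of 9 erythroid genes passed and 9 were higher adjusted over the list alone (median 0.95, camera adjusted p = 1.33e-08, adjusted p = 0.37 with an estimated correlation). Camera called 21 of 34 lists, 0 with an estimated correlation.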

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

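The test of neighbouring genes and the counts of other splits were chosen before their results were seen, and the marrow covariate, the comparison of cell type lists, the comparison of cartilage with fibrous genes, the dilution model and the count of splits balanced by age after. In 691 genes the effect of ENT1 loss differed between 6 and 2 months, by a test of the interaction. Igkv4-72 (2.71 ± 0.52) and Igkj1 (1.68 ± 0.36), immunoglobulin segments, had a larger rise at 6 months. The effect was higher at 6 months by 2.02 ± 0.39 for Epx, 1.93 ± 0.25 for Trav9d-3, a T cell receptor segment, and 1.68 ± 0.28 for Mcpt8, a basophil protease. In genes of skeletal muscle it was lower, with −4.30 ± 0.85 for Myot, −2.67 ± 0.55 for Asb15, −2.51 ± 0.46 for Cox6a2, −2.50 ± 0.54 for Apobec2 and −2.24 ± 0.48 for Tmem182. The mean level of the skeletal muscle list differed between arrays of a group, with −0.92 and 0.15 in 2 month WT and −0.27 and 1.08 in 2 month ENT1-null. The source of the muscle signal in the pools was not tested. All 691 calls ended with all probe sets, and when any single array other than 6 month WT replicate 1 (319 genes) or 2 month ENT1-null replicate 1 (21 genes) was left out.

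In the same interaction 19 lists differed between the ages by camera with a preset correlation, and none with an estimated correlation, where the lowest adjusted p was 0.0986. Medians of the difference were 0.85 for DNA replication and S phase, 1.13 for mitosis and G2/M, and 0.49 for the interferon response (0.23 without 6 month ENT1-null replicate 2, where the call ended). T and NK cells gave 0.81 (0.46 without 2 month WT replicate 2, 0.50 without 6 month WT replicate 2, and not called at 0.84 without 2 month ENT1-null replicate 2). B cells gave 0.74, and macrophages 0.60 (0.95 and 0.18 without 2 month WT replicates 1 and 2, and not called at 0.43 without 6 month ENT1-null replicate 2). Neutrophils gave 1.00, or 1.73 without 2 month WT replicate 1 and 1.78 without 6 month WT replicate 1, and were not called without 2 month WT replicate 2 (0.37), 6 month WT replicate 2 (0.14), 2 month ENT1-null replicate 1 (0.87) or 6 month ENT1-null replicates 1 and 2 (0.95 and 1.04). Medians were −0.34 for fibrous annulus and tendon matrix, −0.49 for cartilage matrix (−0.30 without 2 month ENT1-null replicate 2), −0.37 for collagen and matrix biosynthesis (−0.20 without 6 month ENT1-null replicate 2), −0.34 for TGF-beta and BMP signalling, −0.61 for immediate early genes and −3.09 for skeletal muscle. Wnt signalling gave −0.11 (−0.16 without 6 month WT replicate 2) and hypoxia and glycolysis −0.34 (−0.19 without 6 month ENT1-null replicate 2). Hypertrophic cartilage gave −0.20 (−0.37 without 2 month ENT1-null replicate 1) and was not called without 2 month WT replicate 1 (−0.14), 2 month ENT1-null replicate 2 (−0.11), 6 month WT replicate 2 (−0.13) or 6 month ENT1-null replicate 1 (−0.14). ERK pathway targets gave −0.14, from −0.06 without 2 month ENT1-null replicate 2, where the call ended as it did without 2 month WT replicate 1 (−0.14), to −0.26 without 6 month ENT1-null replicate 2, with −0.22 without 2 month WT replicate 2 and −0.08 without 6 month ENT1-null replicate 1. The circadian clock gave −0.24, or −0.41 without 2 month ENT1-null replicate 2 or 6 month WT replicate 1 and −0.38 without 6 month ENT1-null replicate 2, and was not called without 2 month WT replicate 2 (−0.28), 2 month ENT1-null replicate 1 (−0.26), 6 month WT replicate 2 (−0.17) or 6 month ENT1-null replicate 1 (−0.09). Pericytes and smooth muscle gave −0.30, or −0.45 and −0.11 without 6 month WT replicates 1 and 2, and were not called without 2 month WT replicate 1 (−0.16) or 2 month ENT1-null replicate 2 (−0.15). With the marrow covariate the medians were 0.74 for mitosis, 0.31 for interferon, 0.36 for T and NK cells, 0.49 for B cells and 0.27 for macrophages, and the clock was not called (−0.24).

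The mitosis and G2/M genes rose with the marrow markers in ENT1-null. The other cell types were not raised alike at 6 months, where the skeletal muscle list gave −2.08 and the neutrophil list 2.60. These values were known when the comparison was chosen. They do not decide on a smaller share of annulus cells with unequal changes in the other cell types. The rise at 2 months went with the marrow marker level: with that level as a covariate the effect on the list's mean went from 1.16 ± 0.32 to 0.24 ± 0.16. The WT array with the higher marker level had the higher mitosis level in 28 of 30 genes at 2 months and 30 of 30 at 6 months. The 2 month ENT1-null arrays (marker level 0.39 and 0.47) lay above every WT array (highest −0.23). This fit could therefore not have gone against marrow cells taken with the annulus, and more division is not excluded at 2 months. At 6 months the effect went from 2.19 ± 0.32 to 0.83 ± 0.22, and the mitosis change per unit of marker level was 0.95 there, 0.75 for genotype at 2 months and 1.12 for age in ENT1-null, against 0.43 and 0.68 between the WT arrays of an age, but these ratios rest on 1 or 2 arrays a side, the ENT1-null arrays of both ages lay above every WT array in marker level and the slope was carried past the WT range, so that more division and more marrow cells cannot be told apart there. Of the marrow genes, Ngp was 11.13 and 12.12 in 2 month WT, 12.22 and 11.16 in 6 month WT and 12.88 and 12.84 in 6 month ENT1-null, S100a8 in the same order 9.36, 11.07, 10.74, 9.01, 12.34 and 12.25, and 2 of the 27 marker genes stand in other lists. An effect of genotype and age on cell division, or on marrow cells within the tissue, stays open as well and was not tested.

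The cartilage matrix genes fell in ENT1-null at 6 months by a mean of 0.61, and dilution of every annulus gene alike would lower the fibrous genes as much, whose mean was −0.26, a difference of −0.35 (two-sided permutation p = 0.0269 over 24 and 31 genes, genes being not independent). Without Col1a1 and Col1a2, which bone cells also make, the fibrous mean was −0.37 and the permutation p = 0.0721, so that dilution and a fall of cartilage genes cannot be told apart by this test. For marrow cells alone to give the whole fall they would have to hold 40.3% of the RNA in 6 month ENT1-null, 19.4% in 2 month ENT1-null, 8.87% in 6 month WT and 6.96% in 2 month WT. With the marker level as a covariate the effect stayed at −0.62 ± 0.15 (slope 0.0036), which argues against a straight trend with the log2 marker level as the whole cause, but a share of the RNA is not such a trend: the share model gives −0.21 at 2 months, where −0.15 ± 0.05 was observed, and −0.09 between the arrays of a WT pair, where 0.0031 ± 0.05 was observed. These values are within 2 SE of the model, so that marrow dilution and an effect of genotype on cartilage cells cannot be told apart.

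The genes near Slc29a1 were asked for alleles of the strain in which the deletion was made. Of the 200 tested neighbours on chromosome 17, 84 (42%) had an unadjusted p below 0.05 across ages against 40.0% of other genes, an odds ratio of 1.09 (95% interval 0.81 to 1.45, Fisher's exact two-sided p = 0.562). At 2 months the shares were 23% and 19.3%. No excess near Slc29a1 was found, and across ages odds ratios above 1.45 lay outside the interval. Flanking alleles that change single genes are not excluded, and 200 neighbours could not hold many of the calls in any case. For the 3809 genes changed by genotype across ages the real split was the only 1 of 34 splits of the 8 arrays with as many genes. The highest of the others gave 0. This count takes each array as a separate sample, and part of the 34 splits mix the ages, which the design does not. The splits that keep 2 and 2 arrays at each age are 18, with a lowest possible share of 0.0556. They are too few for a share under 0.05, so that they cannot exclude chance. For the 77 genes changed by age across genotypes chance cannot be excluded, since 2 of 34 splits gave as many and the highest of the others gave 553. That split, with 2 month WT replicate 1, both 2 month ENT1-null arrays and 6 month WT replicate 2 on 1 side, points to a structure of the samples: within each genotype it parts the arrays by marrow marker level.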

How the results depend on the processing

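The marrow covariate and its values were chosen after seeing the data. The cause of each change below was not tested, except where fewer genes or arrays or another threshold make it. Of the 298 named gene results, 293 kept their direction and side of the threshold with arrays centred on their medians (5 came to pass), 292 with quantile normalization again, 249 with no filter, 223 with all probe sets, 242 with the replicate block, 275 with eBayes trend and robust, and 78 with the marrow covariate (211 no longer passed, 9 reversed). Of the called lists 103 were followed, not every one, and 103 of these kept theirs under centring, quantile normalization and trend, 102 under no filter and the block, none with an estimated correlation, 48 with fry. The labels tie the replicate numbers to no animal, batch or day. Deviations from the group means of same-numbered arrays went together between the 2 month groups (r = 0.41 across genes) and had r from −0.39 to 0.15 between the other groups. The signal over background and 2 arrays per group limit what can be detected.

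Genes changed by genotype at 2 months (106) numbered 29 with no filter, 161 centred, 0 with all probe sets, 1 with the block, 259 with trend and robust, and 0 with only the groups compared. They numbered 823 at adjusted p below 0.1, 791 at unadjusted p with a 1.5-fold difference, 0 with the marrow covariate, and from 0 (without 2 month WT replicate 1 or ENT1-null replicate 2) to 358 (without 2 month WT replicate 2) with single arrays left out. At 6 months (6022) they numbered 3072 with the 1.5-fold difference, 0 with the marrow covariate, and 3670 (without 6 month WT replicate 2) to 5887 with arrays left out. In the interaction (691) the counts were 11 with no filter, 0 with all probe sets, 353 with the block (155 higher, 198 lower, against 398 and 293), 1102 with trend, 2383 at 0.1, 1896 at 1.5-fold, 0 with the marrow covariate, and 0 (6 of the arrays) to 319 (without 6 month WT replicate 1). Across ages (3809) they were 1614 at 1.5-fold, 0 with the marrow covariate, and 1390 (without 6 month WT replicate 1) to 4343 (without 2 month ENT1-null replicate 1). Changed by age in WT (0) were 278 at 1.5-fold. In ENT1-null (3442) they were 1944 at 1.5-fold, 301 with the marrow covariate, and 1519 (without 2 month ENT1-null replicate 1) to 3160. Across genotypes (77) they were 40 with no filter, 157 with the stricter filter, 9 with all probe sets, 0 with the block, 767 at 0.1, 536 at 1.5-fold, 0 with the marrow covariate, and 0 to 610 (without 6 month WT replicate 2).

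The called lists (21, 21, 19, 20, 16, 23 and 21 in the 7 comparisons in the order of the report) were 0 in each with an estimated correlation. With fry they were 0, 22, 2, 12, 1, 14 and 7, and with the marrow covariate 7 at 2 months and 8 across ages, and at 2 months 11 (without 2 month ENT1-null replicate 2) to 22 with arrays left out. Slc29a1 at 2 months no longer passed with all probe sets (−1.41), with only the groups compared (−1.41) and with the marrow covariate (−1.33), nor without 2 month WT replicate 1, 2 month ENT1-null replicate 1 or 2 month ENT1-null replicate 2, with values between −1.48 and −1.34 when arrays were left out. At 6 months it gave −1.40 and did not pass with the marrow covariate. Reversed under the marrow covariate across ages were Ctsg (−0.71) and Fcnb (−0.22), which are themselves among the genes that make it. Also reversed across ages were Atp8b4 (−0.24), Ifitm6 (−0.46), a kappa variable segment (−2.01), Jchain (−0.64) and Ly6g (−0.41). At 6 months Ifitm6 (−0.19) and the kappa segment (−3.35) reversed, as did the endothelial list (−0.035), by the direction of the test. Without a turn of that direction the medians of the skeletal muscle (−0.10) and nucleoside lists (−0.06) at 2 months and of mitosis by age in WT (−0.04), among others, lay below 0. Reversed without 6 month WT replicate 1 were the S phase and mitosis lists by age in WT, which ranged from −0.04 and −0.23 there to 0.23 and 0.48 without 6 month WT replicate 2.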

Other observations

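The test of glucocorticoid-responsive genes and that of the Dlk1-Dio3 region were chosen after the result was seen. Genes that lie between Dlk1 and Dio3 in their imprinted region of chromosome 12, which holds the noncoding RNAs Meg3 and Rian and a large cluster of microRNAs, were lower in ENT1-null at 6 months. Dlk1 itself, at the end of the region, was not counted with them and moved the other way by genotype. It rose by 0.74 ± 0.09 at 2 months (limma adjusted p = 0.0388) and by 0.30 ± 0.09 at 6 months (limma adjusted p = 0.0302). Its 2 month call ended without 2 month WT replicate 1, either 2 month ENT1-null array or either 6 month ENT1-null array. It also ended with all probe sets, the replicate block, only the groups compared or the marrow covariate. With age in ENT1-null Dlk1 gave −0.58 ± 0.09 (limma adjusted p = 0.00488), the direction of the median of the region. Of the 32 tested genes between Dlk1 and Dio3 (23 of them microRNA genes) 28 were lower in ENT1-null at 6 months, against 17.4% of the other 15494 genes, Dlk1 among these (median −0.95, Fisher's exact p = 1.09e-17, tested on the data in which it was noticed, in genes that are not independent). Rian gave −1.18 ± 0.09, Meg3 −0.73 ± 0.18, AF357425 −1.81 ± 0.25 and Mir453 −1.73 ± 0.09, all chosen after their values were seen. At 2 months the median of the 32 was −0.06 with 1 lower and 0 higher, and in the interaction it was −0.77 with 11 lower. With age the median was 0.01 in WT with none lower by limma and −0.78 in ENT1-null with 24 lower. In the same comparisons the skeletal muscle list gave −2.08 for genotype at 6 months, 0.96 at 2 months, 1.55 for age in WT and −1.56 for age in ENT1-null. In that order the neutrophil list gave 2.60, 1.5, −0.06 and 0.95 and the erythroid list 2.20, 1.73, 0.63 and 1.21. With the marrow covariate, chosen after seeing the data, the median of the 32 genes was −0.67 for genotype at 6 months, 0.06 at 2 months, −0.68 in the interaction and −0.63 for age in ENT1-null.

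Other cell type lists were not called in the genotype comparison at 6 months. The osteoblast and osteocyte list (14 genes, median 0.12) had 5 higher, 1 lower and 8 not passing, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.41). Bglap, osteocalcin (1.04 ± 0.20), and Dmp1 (0.86 ± 0.21), chosen after their values were seen, rose. The nucleus pulposus and notochord list (13 genes, median −0.29) had 2 higher, 4 lower and 7 not passing, with 3 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.259). The Y-linked gene Uty lay between 8.63 and 8.93 on all 8 arrays and Xist between 5.39 and 5.75, with no array apart.

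A hypothesis formed after the falls had been seen, Zbtb16 among them, is that glucocorticoid signalling was lower in ENT1-null. A list of 25 glucocorticoid-responsive genes, made then and without the 4 already seen among the lowest falls, had a median of −0.27 across ages, with 20 of 25 below 0 and 6 lower. Its test was not called with an estimated correlation (camera over n = 25 genes, p = 0.00333, and p = 0.219 with an estimated correlation). At 2 months none of the 25 passed (median −0.38, 21 below 0, camera over n = 25 genes, p = 0.000138, and p = 0.198 with an estimated correlation), and with the marrow covariate limma's camera gave p = 0.17 (n = 25 genes, median −0.14, 17 below 0). At 6 months 6 were lower and 1 higher (median −0.15, 15 below 0, camera over n = 25 genes, p = 0.0605), and the marrow covariate turned the median to 0.17 there. Across ages with the marrow covariate limma's camera gave p = 0.255 (n = 25 genes, median −0.13, 17 below 0). Since the marker level and the genotype overlap, lower glucocorticoid signalling and a change in the cells sampled cannot be told apart.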
